A study of Oryzias latipes with 2 samples.

How the data were processed

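RNA was extracted with Trizol from whole medaka embryos, 60 per sample, and sequenced on an Illumina HiSeq 2000, per the labels' protocols and the series' design text. The 2 samples are replicates of 1 group at stage 24. The labels call the material total RNA and name no selection of messenger RNA. Whether the library or the counting kept the strand is not given in the sources used here, so values of genes with an overlapping antisense gene are uncertain. TopHat, a spliced-read aligner, is named in the submitters' processing notes with no version. The counting program, the genome build and the annotation release are not given in the sources used here.

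For each sample the authors deposited a table with a raw read count and an RPKM value per gene entry, per the file headers, with the Ensembl gene and transcript identifiers. The authors' counts are whole numbers with different totals in the 2 samples. The authors' RPKM values of entries with 1 transcript divide the count by a length and the library total. For all entries with 1 transcript and any read (14406 in replicate 1, 14416 in replicate 2), count and RPKM together gave a whole-number length within 0.001 bp, for a library total of 22650004 reads in replicate 1 and 23045699 in replicate 2. The lengths were equal in the replicates for all 14009 such entries with reads in both, and they are known only for entries with a read. Of the known lengths, 73.4% were multiples of 3, and whether they span whole transcripts is not known. For entries with several transcripts, 38.7% in replicate 1 and 39.2% in replicate 2 gave a whole length, so the divisor of the others was not a whole length. For some entries with several transcripts the RPKM moved without the counts. Of 3382 with at least 20 reads, the log2 ratios of the replicates in counts and RPKM differed by more than 0.1 for 390. The tables list 20259 entries in the same order. Of these, 3895 hold several transcripts, 168 join 2 or 3 genes under 1 count, and 13 gene identifiers occur on more than 1 line. Entries were kept as deposited. The counts sum to 0.0494% more than the library total in replicate 1 and 0.0441% more in replicate 2.

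Levels were summarised as deposited RPKM, with 1 RPKM as the detection level. Replicates were compared as log2((RPKM + 1) of replicate 2 over replicate 1), which understates the change of low genes. Counts were compared with the split of reads expected from the total counts. The ratio of the squared difference to its binomial variance was averaged over entries with at least 10 reads in the replicates together, and exact binomial tests were adjusted by the Benjamini-Hochberg method. The biological coefficient of variation was estimated in edgeR 4.0.16 (R 4.3.3) with trimmed-mean scaling and an intercept as the only term. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. With 22661195 and 23055861 counted reads, expressed entries had a median of 978 reads over both replicates.

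The procedures were tested on simulated counts drawn from the observed means. The variance ratio came out at 0.997 for sampling noise alone over 16593 entries. The binomial test recovered 83% of 200 genes changed 2-fold, with 8 false calls among 16554 entries. It recovered 93% of 200 genes changed 4-fold, with 47 false calls among 16591. In the 4-fold simulation, false calls thus made up more of all calls than the adjusted p threshold of 0.05 is meant to allow. Why the test missed its nominal rate there was not tested. The libraries simulated for this test held sampling noise only. Its false calls therefore do not carry over to libraries that differ by more than sampling noise. Simulated coefficients of variation of 5% and 20% were estimated by edgeR at 4.91% and 19.8%.

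Before the data were examined, the detection count, the replicate spread and 4 further analyses were fixed: levels of 42 gene lists, differences of those lists between replicates, Hox levels by paralogue group, and regulators against products of the same tissue. Those 4 need gene names. The reference gene list at hand, of assembly ASM223467v1, carries no Ensembl identifiers, none matched, and the 4 analyses and the 42 lists were not run. The rule for named genes then allowed at most 2 identifiers at each end: the highest mean RPKM, and the largest log2 differences between replicates among entries with a mean of at least 5 RPKM. The count-based analyses, the abundant class, and the comparisons by number of transcripts, by length and of adjacent entries were chosen after the tables were seen. Alternatives were computed for the detection count, the 2-fold count and the median ratio of the replicates, the variance ratio, the binomial calls, the abundant class, the comparison by number of transcripts, adjacent entries and the length trend. None were computed for the correlations of the replicates or the edgeR estimate.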

Results

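Transcript levels were measured by RNA sequencing in whole medaka embryos (Oryzias latipes, a small freshwater fish used as a vertebrate model) at stage 24, a stage of mid-somitogenesis at about the time the heart starts to beat. The sample titles name ICab, a laboratory medaka strain. There was 1 group with 2 replicates, each a pool of 60 embryos raised at 26 °C and freed of the chorion by hand. No treatment, genotype or second stage was compared, so the design asks which genes were expressed at this stage, at what level, and how closely 2 pools agreed. The labels do not say whether the pools came from separate clutches or days, and the spread between them may therefore be technical. Replicate 1 held 22661195 counted reads and replicate 2 held 23055861, over the same 20259 gene entries. A gene entry is 1 line of the deposited tables, usually 1 Ensembl gene. Neither the tables nor the gene list at hand pairs these identifiers with gene names, so genes are given by identifier and no tissue or pathway group is described.

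Most annotated genes were detected at stage 24. In both replicates, 14097 entries, or 69.6% of the total, reached at least 1 RPKM (reads per kilobase of transcript per 1000000 reads). Replicate 1 had 14378 such entries, replicate 2 had 14365, and 549 entries passed in one replicate but not the other. The most heavily filled range was 16 to 32 RPKM, with 3024 entries by the mean of the replicates, followed by 8 to 16 RPKM with 2725. Median levels were 7.71 RPKM in replicate 1 and 7.65 RPKM in replicate 2. A further 3952 entries had reads but stayed under 1 RPKM in both replicates. No read was counted in either replicate for 1661 entries, 8.20% of the total. For these, a count of 0 over both libraries allows up to 3 reads, or 0.0657 reads per 1000000. Silent genes and genes below this limit were not separable at this depth. The limit in RPKM depends on transcript lengths, which are not known for entries without reads.

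A small set of very abundant genes took a large part of the transcripts. Entries at 2048 RPKM or more numbered 88 by the mean of the replicates, 87 in replicate 1 and 88 in replicate 2. These entries held 33.1% of the summed RPKM and 22.2% of the reads in replicate 1, and 33.8% and 22.9% in replicate 2. In the histogram of levels the number of entries fell from 90 between 512 and 1024 RPKM to 43 between 1024 and 2048 RPKM, and then stood at 67 between 2048 and 4096 RPKM. The abundant entries were short. The 66 of them with 1 transcript had a median length of 523.5 bp, against 1167 bp for the 14813 entries with 1 transcript and any read. By reads alone, without division by length, 86 of the 88 were among the 200 entries with most reads, but the histogram of counts per 1000000 showed no second rise.

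**Figure D1:**
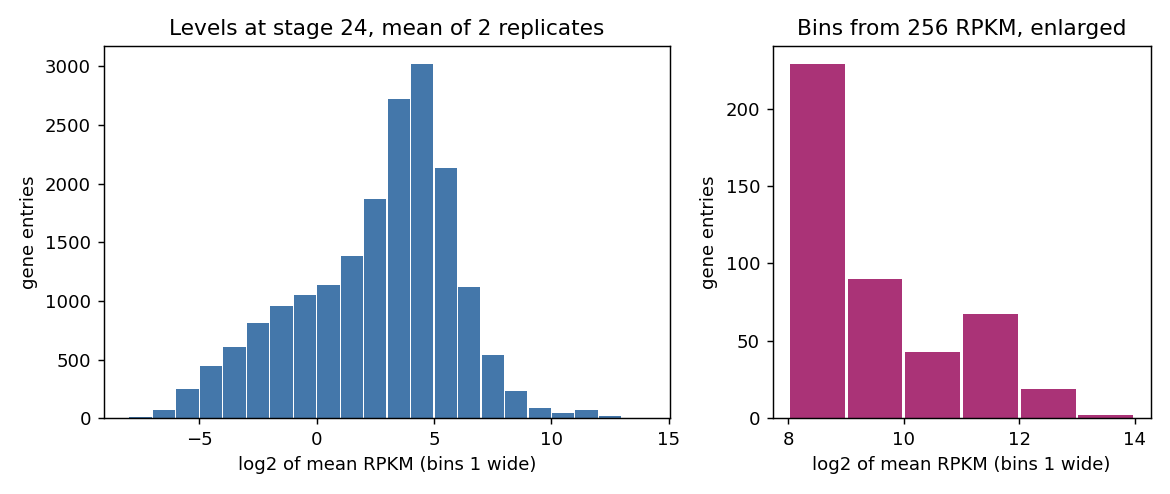
Number of gene entries (y axis) per bin of log2 mean RPKM of the 2 replicates (x axis, bins 1 wide); the right panel enlarges the bins from 256 RPKM upward. The fullest bin is 16 to 32 RPKM with 3024 entries, and 67 entries between 2048 and 4096 RPKM stand above the 43 in the bin before.

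The most abundant entry was ENSORLG00000007614, a gene with 1 transcript of 1646 bp. It reached 10179.8 ± 97.9 RPKM (SD, n = 2) from 376944 reads in replicate 1 and 388779 in replicate 2. Its share of all counted reads was 1.66% in replicate 1 (95% exact Clopper-Pearson interval 1.66% to 1.67%) and 1.69% in replicate 2 (1.68% to 1.69%). These intervals cover counting error only, since reads copied during amplification are not independent molecules. The next entry joined the genes ENSORLG00000012618 and ENSORLG00000012625, whose reads were counted together, and reached 8807.8 ± 299.9 RPKM (SD, n = 2). It took 1.13% of the reads in replicate 1 and 1.20% in replicate 2. The 10 entries with most reads held 7.72% of the reads in replicate 1 and 7.81% in replicate 2. The top 100 held 25.8% and 26.2%, and the top 1000 held 57.2% and 57.6%.

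Genes annotated with several transcripts had higher RPKM values than genes with 1 transcript. Their median was 13.3 RPKM (interquartile range 1.88 to 36.1, 3895 entries), against 6.63 RPKM (0.459 to 24.3, 16364 entries). The difference of medians was 6.69 RPKM, with p = 1.0e-05 in a two-sided permutation test over entries with 100000 resamples, the smallest p these resamples can give. Without the 168 entries that join genes, the medians were 12.5 and 6.63 RPKM. In counts per 1000000, which are not divided by length, they were 18.1 and 7.20 with joined entries kept. Each of these 2 comparisons gave p = 1e-04 in a two-sided permutation test with 10000 resamples, the smallest p these can give. Longer transcripts collect more reads, and lengths of entries with several transcripts are not known. The counts therefore do not remove length from the comparison. For most entries with several transcripts the divisor of the RPKM was not a whole length, and for some it differed between the replicates. Neither unit therefore settles whether expression itself was higher. The difference in RPKM stood in each replicate alone, with medians of 13.2 and 6.62 RPKM in replicate 1 and 13.1 and 6.54 RPKM in replicate 2. Detection at 1 RPKM in both replicates was also more frequent, at 78.6% against 67.4% (odds ratio 1.77, p = 4.57e-44, Fisher's exact test, two-sided). Entries that join several genes were higher still, with a median of 38.4 RPKM over 168 entries, a difference that was not tested. Genes are not independent replicates, and these p-values describe the entries of the annotation in these libraries. Transcript length showed almost no relation with level across the 14813 entries with 1 transcript and any read (Spearman's rho = -0.01). Ranks and medians do not describe the most abundant entries, which were short. Of 10 groups of equal size by length, the shortest, up to 453 bp, had a median of 5.69 RPKM, and the medians of the others lay between 7.999 and 9.74 RPKM.

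The 2 pools of embryos gave closely similar levels for most genes. Across all 20259 entries, log2(RPKM + 1) correlated between the replicates with Pearson's r = 0.996, and Spearman's rho of the RPKM was 0.993. These are correlations across genes within 1 pair of samples. Among the 14385 entries with a mean of at least 1 RPKM, the median absolute log2 ratio on the log2(RPKM + 1) scale was 0.09, a 1.06-fold difference, and 92.6% of entries differed by less than 1.25-fold. The median absolute log2 ratio was 0.17 for the 3031 entries from 1 to 5 RPKM, 0.10 for the 5024 entries from 5 to 20 RPKM and 0.07 for the 5037 entries from 20 to 100 RPKM. It was 0.05 both for the 1161 entries from 100 to 1000 RPKM and for the 132 entries above. The biological coefficient of variation, estimated from the counts with edgeR across 16588 entries with at least 10 reads, was 3.92%. The estimate that varies with expression level had a median of 5.20% and ran from 3.07% to 20.5%. The word biological is the method's name. These values hold any difference between the 2 libraries beyond counting noise, whether from the embryos or from library preparation.

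**Figure D2:**
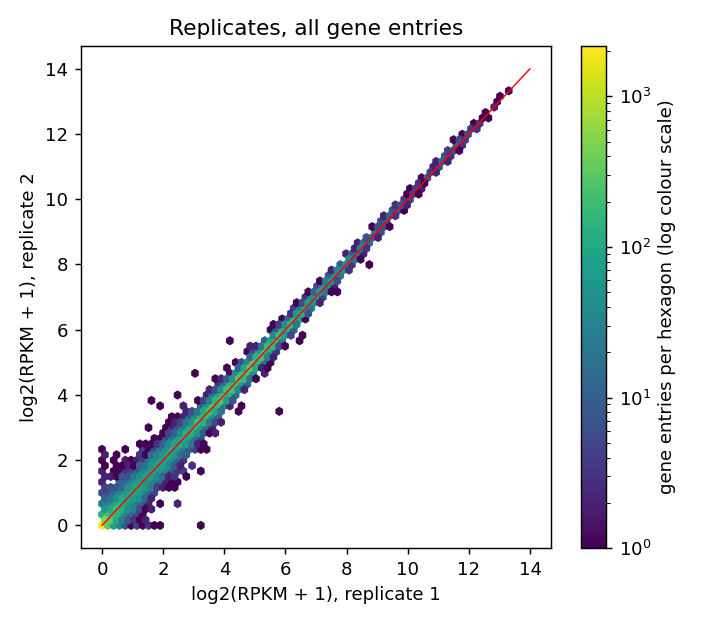
Level of each gene entry in replicate 1 (x axis) and replicate 2 (y axis), both as log2(RPKM + 1); the colour gives the number of entries per hexagon on a log scale and the red line marks equal levels. Entries lie along the line at all levels, with Pearson's r = 0.996.

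Genes that differed more than 2-fold between the pools on the log2(RPKM + 1) scale were mostly very short genes with few reads. They numbered 48 of the 14385 from 1 RPKM, with 28 higher in replicate 2 and 20 higher in replicate 1. Of these, 41 had fewer than 100 reads in the replicates together, and the 44 with 1 transcript had a median length of 100.5 bp. An entry with few reads reaches 1 RPKM only if it is short. The filter itself thus favours short entries among those with few reads. Among entries with a mean of at least 5 RPKM, the largest excess in replicate 2 was ENSORLG00000021283, a 78 bp gene with 4 reads in replicate 1 and 24 in replicate 2, a log2 difference of 2.14. ENSORLG00000021299, of 84 bp, followed with 5 and 22 reads and a log2 difference of 1.77. In the other direction ENSORLG00000021665, of 88 bp, had 17 and 4 reads and a log2 difference of -1.68. The largest deficit in RPKM was ENSORLG00000020638, a gene with several transcripts, at 55.2 RPKM in replicate 1 and 9.73 RPKM in replicate 2, a log2 difference of -2.39. Its counts of 2462 and 2398 reads differed by only 1.04-fold after scaling to the library totals, so the RPKM and the counts of this gene gave different answers. The same held for all 4 of the entries with several transcripts among the 48: the counts of each differed by less than 2-fold. The number of entries more than 2-fold apart was 12 at a mean of at least 5 RPKM, 128 with a pseudocount of 0.1 and 3 in counts per 1000000 with a mean of at least 1. With no pseudocount, it was 248 in counts and 257 in RPKM among entries with at least 20 reads and a read in each replicate.

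The counts were set against sampling noise to see whether the same library might stand under both labels. The squared difference from the expected split of reads was on average 2.86 ± 0.0754 times the sampling variance (SE over 16588 entries with at least 10 reads). Ideal sampling of reads from a single library would give 1, and separately prepared pools would be above it. A ratio above 1 does not by itself show separate libraries, since for a single library only ideal sampling was simulated. With 1 library against 1, no test across replicates is possible for any gene. Exact binomial tests on the reads of each entry compare these libraries and not any condition, and they cover counting error only, which the variance ratio shows to be smaller than the observed spread. They called 1009 of the 16588 entries at an adjusted p under 0.05 (Benjamini-Hochberg). Of these calls 446 were higher in replicate 2 (44.2%) and 563 higher in replicate 1. With the libraries scaled to a median log2 ratio of 0, 955 entries were called and 542 of them (56.8%) were higher in replicate 2, so the direction of the majority rested on the scaling. When the sampling variance was scaled by the observed mean ratio, 58 entries were called. All were among the 1009, which a wider variance makes nearly certain. The same factor served every entry, although the mean ratio was 1.67 for entries with 10 to 34 reads and 9.01 for those with 5114 or more. Taken from medians in place of means, the ratio was 1.64 and 5.19 in these bins. The factor was thus too strict for entries with few reads and too lenient for those with most.

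**Figure D3:**
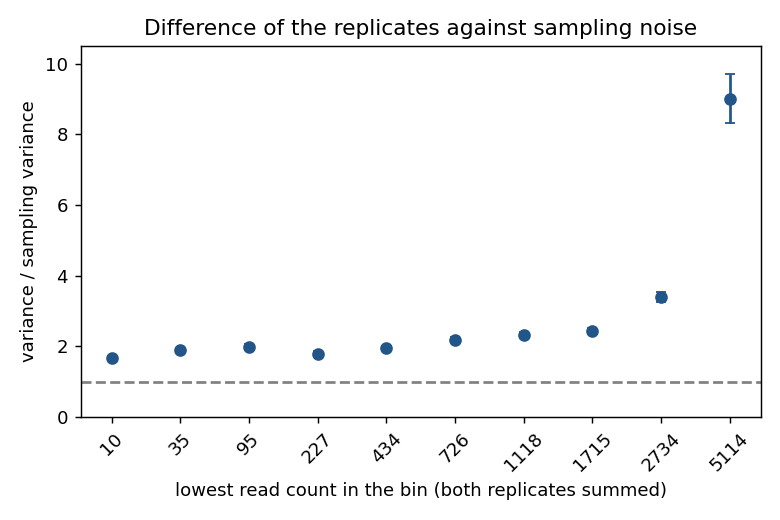
Mean ratio of the squared replicate difference to the sampling variance (y axis, points with SE over entries as bars) in 10 bins of entries ordered by reads summed over both replicates (x axis, labelled with the lowest count of each bin). The dashed line marks sampling noise alone at 1. The mean ratio runs from 1.67 in the lowest bin to 9.01 in the highest, where the ratio taken from medians, not drawn, is 5.19.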

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

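The number of entries detected in both replicates, 14097 as reported, depended on the threshold. It was 17671 with any value above 0, 15060 from 0.5 RPKM and 11169 from 5 RPKM. With at least 10 reads in each replicate it was 15425. Single-transcript entries alone gave 11036, a count over fewer entries. With 1 replicate left out it was 14365 to 14378. The number of entries more than 2-fold apart depended on the settings: 48 as reported, 12 at a mean of at least 5 RPKM, 128 with a pseudocount of 0.1, and 3 in counts per 1000000 (CPM) of at least 1. It was 9 with that CPM filter on RPKM ratios and 3 for CPM ratios with the RPKM filter. With no pseudocount, from 20 reads, it was 248 in counts and 257 in RPKM. The median absolute log2 ratio of 0.0858 became 0.0820 without a filter, 0.0750 from 5 RPKM, 0.0931 with a pseudocount of 0.1, 0.0836 with the CPM filter, and 0.1005 in counts and 0.103 in RPKM with no pseudocount. The variance ratio of 2.86 became 3.04 from 50 reads, 3.62 from 500 reads and 2.26 without the 1000 entries with most reads. Scaling the variance left 58 of 1009 binomial calls. Entries at 2048 or more numbered 87 to 88 with 1 replicate left out and 46 in counts per 1000000, which do not divide by length. Alternatives on counts, single-transcript entries and 2048 RPKM were chosen after seeing the data. The spread has no value with 1 replicate. Alternatives of the 4 analyses that need gene names were not run. No paired analysis was possible because there is 1 group. Depth limits the lowest entries: 41 of the 48 had under 100 reads.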

Other observations

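Tests chosen after the results were seen were those of length and of single bins for the second peak, of pairs with at least 1000 reads, of pairs under the median or of known length, those of the excess noise, and the relation of length to the replicate ratio. The bootstrap of the second peak was written down first, and its limited power was judged afterwards. Also written first were the tests of adjacent entries from the median length, from 1 RPKM, and without joined or repeated entries.

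Levels of neighbouring gene entries were weakly correlated. Across 20258 pairs of adjacent entries in the deposited order, Spearman's rho of mean RPKM was 0.17, against at most 0.02 in 100 random orders. It was 0.08 at a distance of 2 entries, 0.05 at 3, 0.03 at 5 and 0.01 at 10. Each replicate alone gave 0.16. Whether the deposited order follows the chromosomes is not given in the sources used here. Joined or repeated entries do not account for it, since rho was 0.163 without them. Reads counted in more than 1 entry stay open: rho was 0.0719 over 2828 pairs in which both had at least 1000 reads, and where such reads lie is not known. A gene split into neighbouring short entries may still contribute: rho was 0.0941 over 2980 pairs in which both were at least of median length and 0.183 over 3064 pairs in which both were shorter, but lengths are known only for entries with 1 transcript and a read, and rho was 0.0966 over the 11065 pairs in which both were such entries. Runs of silent genes may contribute too, since rho was 0.0599 when both entries were at 1 RPKM or more, a filter that also narrows the range of levels. Shared regulation of neighbours is a hypothesis that stays untested.

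The second peak in the histogram, with 67 entries from 2048 to 4096 RPKM above 43 in the bin before, is not shown to be more than chance. A bootstrap from the closest density that only falls above 32 RPKM gave p = 0.731 (n = 4246 entries), but the same test found a planted peak of 88 entries in 0 of 40 simulations of this size, so it cannot decide. An exact binomial test of those bins, which were picked by eye, gave p = 0.0279. Division by length stays open as a source: the abundant entries were short and the histogram of counts per 1000000 had no second rise. Entries of like length had a median log2(RPKM + 1) 0.0737 above that of all entries with 1 transcript and reads, but a median does not describe the top of the range. No biological explanation was tested, since the genes have no names here.

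Separately prepared pools would differ by more than sampling noise in any case, so an excess would by itself be no finding. Whether these pools came from separate clutches or days is not given, and the source of the excess stays open. At low counts the variance ratio was 1.67 ± 0.0555 (SE) for entries with 10 to 34 reads, and it was 1.95 ± 0.0664 for entries with 434 to 725 reads. Counting both mates of every fragment is excluded, because even numbers made up at most 0.510 of counts from 101 to 1000; a mixture of single and paired counts is not excluded. Reads copied in library amplification may add such noise and cannot be told apart from differences between the pools of embryos, since counts per gene hold no read positions and the ratio of 1.67 at low counts is open to both.

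For entries with several transcripts, the RPKM varied more between the replicates than the counts did. Over 3382 such entries with at least 20 reads, the median absolute log2 ratio of the replicates was 0.0861 in counts and 0.0958 in RPKM, and for 390 of them the log2 ratios in counts and RPKM differed by more than 0.1. More than 2-fold differences numbered 56 in counts and 65 in RPKM, with 50 shared. In the 12315 entries with 1 transcript the median was 0.105 and 192 entries differed by more than 2-fold, in either unit.

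Short transcripts had slightly more reads, relative to long ones, in replicate 2. With 1 library against 1, a difference between the embryos and one of library preparation cannot be told apart here. Across 9112 entries with 1 transcript and at least 200 reads, length and the log2 ratio of replicate 2 over replicate 1 had a Spearman's rho of -0.13. The median log2 ratio ran from 0.03 in the shortest eighth (75 to 591 bp) to -0.04 in the longest (3084 bp and over). The rho was -0.21 from 1000 reads and -0.12 under 500 RPKM. There were 6 entries with no read in one replicate and at least 10 in the other, 5 of them with reads in replicate 2.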
